A study of Mus musculus with 6 samples.

How the data were processed

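Livers of 8-week-old male C57BL/6 mice were measured by RNA sequencing in 3 vehicle and 3 iD1 samples. Per the labels' protocols, a drug was given by intraperitoneal injection, RNA was taken with TRIzol and RNeasy columns, and libraries were made with a stranded mRNA kit. The authors deposited 1 table of estimated counts per gene, not scaled to depth, with versioned Ensembl identifiers. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. Between 22.6% and 27.7% of the values in a library were not whole, and the deposited estimated counts were rounded to whole numbers before any test. Reads that fit several copies of a gene can be shared out by such estimates, which makes single values of near-identical genes uncertain.

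Symbols were found for 34582 of the 34866 identifiers. With GENCODE M21 on GRCm38, 93.6% of the versioned identifiers and 99.4% of the identifiers without version matched, and positions were taken from that annotation. Columns were assigned to samples by name. A vehicle column with a number that no sample title has was used as a vehicle replicate without a number. No pair of libraries of the same group agreed within sampling noise, so none was counted as a duplicate. Pairs across the groups were not checked in this way.

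Totals ranged from 23515571 to 37613549 estimated counts per library. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13718 genes, and 11664 genes had no count. Libraries were scaled by TMM, with factors from 1.01 to 1.11 in vehicle and from 0.878 to 1.01 in iD1. Groups were compared with edgeR's quasi-likelihood F test (robust, two-sided, edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes, and SDs are over 3 libraries. With 3 libraries against 3, an exact permutation test of a single value cannot go under 0.1, so p-values come from models fitted across genes.

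Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 48 lists with at least 5 tested genes. The counts of called members were also adjusted over the list alone. The 49 lists covered metabolism, nuclear receptor targets, stress, inflammation, zonation, handling and RNA quality, and markers of other cell types, and overlap in part.

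The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, among called genes with non-overlapping groups and a mean of at least 1 CPM in a group, the 10 largest changes in each direction, then the 6 smallest p-values, and of each list up to 4 called members by smallest p, or up to 2 members given as values where none was called. Predicted genes were counted and not described, and a few genes that the rule takes are not reported here. Some further genes were chosen after their values were seen, and the text says so.

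The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, other filters, a stricter threshold, a test against a fold of 1.2, non-robust shrinkage, a replicate block, thinning to the smallest total, leaving out each library, and for lists an estimated correlation, fry and ranks. Removing each library's trend on GC content and gene length, from the longest GENCODE M21 transcript of 99.6% of the tested genes, was added after the data were seen.

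The gene and list tests were tested on simulated data made from the means and library sizes of iD1 against vehicle over 13718 genes. Of genes changed 1.5-fold, 18.2% were recovered, of those changed 2-fold 64.2% and of those changed 4-fold 89.6%. There were 14 false calls among 13418 unchanged genes. The correct calls numbered 12, 43 and 60 for these folds and 12 among members of lists raised 1.5-fold. The false calls were thus a larger share of all calls in this simulation than the adjusted p threshold. Camera called 5 of 5 raised lists and 0 of 45 unchanged lists. The simulated genes varied independently of each other, unlike genes in a liver, so this does not measure false calls of lists whose members vary together.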

Results

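Polyadenylated RNA was measured by sequencing in the livers of 8-week-old male C57BL/6 mice given either vehicle or iD1, a compound known here only by its code name. The labels do not state its dose, exposure time or target. There were 6 libraries in 2 groups of 3. The treatment label of the vehicle samples reads untreated. Their titles and the design text name a vehicle, and they are called vehicle throughout. One column of the count table carries a vehicle number that no sample title has, and it was used as a vehicle replicate without a number. The labels do not say that the libraries of a group came from different animals, so p-values measure the spread between these samples. The totals were 27160894, 37613549 and 32342898 estimated counts in the vehicle libraries and 24694639, 35207596 and 23515571 in the iD1 libraries. Of 34866 genes in the table, 13718 had enough counts to be tested.

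The 2 groups separated on the first principal component, which held 56.8% of the variance, with iD1 replicate 1 placed nearer to the vehicle libraries than the other iD1 libraries. The correlation of log2 CPM across genes ranged from 0.981 to 0.987 within vehicle, from 0.974 to 0.980 within iD1 and from 0.944 to 0.967 between the groups. Mitochondrially encoded genes took 12.2% ± 1.49 of the counts in vehicle and 9.44% ± 0.802 in iD1 livers (SD, n = 3 each), and the groups did not overlap in this share.

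**Figure D1:**
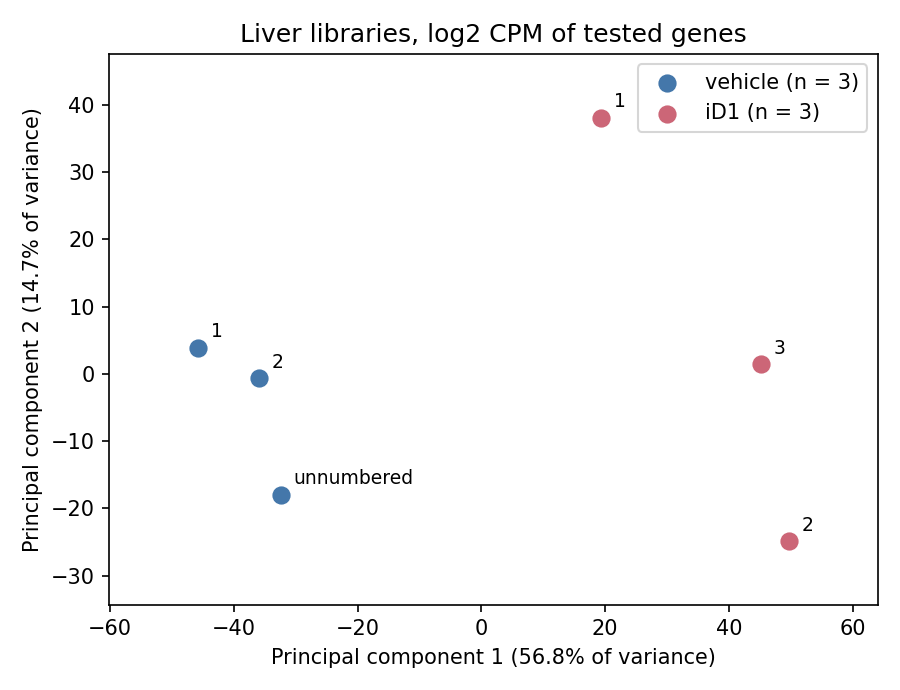
Principal components 1 and 2 of the log2 CPM values of the tested genes, with 1 point per library, coloured by group and marked with its replicate number. The 3 vehicle libraries lie on the left and the 3 iD1 libraries on the right of component 1, which holds 56.8% of the variance.

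The comparison of iD1 with vehicle asks which liver transcripts differ after treatment with the compound. Changes were ranked only among called genes with non-overlapping groups and a mean of at least 1 CPM in a group. Among these, the transcripts that rose most in iD1 livers encode the metal-binding metallothioneins Mt2 and Mt1, the glycogen-targeting phosphatase subunit Ppp1r3g and the iron-scavenging lipocalin Lcn2. Next came the insulin-like growth factor binding protein Igfbp1, the transcription factor Egr1, the chemokine Cxcl1, the integrin subunit Itga2, the G-protein regulator Rgs16 and the heat shock protein Hspa1a. Mt2 went from 5.18 ± 5.55 CPM in vehicle to 1465 ± 345 CPM in iD1 livers (SD, n = 3), and Igfbp1 from 16.2 ± 8.86 to 1117 ± 540 CPM. The largest falls, ranked likewise, included Clic3, Angptl8, Pdxp, the lipid droplet protein Pnpla3, the histone gene Hist2h3c2, Zfp872 and the calcium pump Atp2b2, together with 3 predicted genes. Clic3, Pdxp, Hist2h3c2, Zfp872 and Atp2b2 were low already in vehicle, from 1.43 CPM for Pdxp to 3.28 CPM for Atp2b2 on average. Their total counts over the iD1 libraries ran from 7 for Pdxp to 28 for Atp2b2. Exons of Pdxp share 903 bases on the same strand with Gm49510, which was not tested, so reads of the pair may be mixed. Angptl8, a feeding-induced regulator of lipoprotein lipase, went from 137 ± 70.8 to 8.76 ± 3.27 CPM. The 6 smallest p-values belonged to Junb, Cxcl1, Itga2, the interleukin 1 receptor Il1r1, Btg2 and Tmem87b, all higher with iD1. Junb had a log2 fold change of 4.28 (SE 0.16) and an adjusted p of 3.06e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

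In that test 2293 genes passed an adjusted p of 0.05, 1155 of them higher and 1138 lower with iD1, and 908 of the 2293 differed at least 2-fold. The values of the groups did not overlap in 5100 tested genes, which is 37.2%. Chance gives 10% on average over all splits of the libraries. Genes that vary together can move the share of a single split away from that average, so the 10% is no test of the 37.2%. The share of called genes that were higher was 50.4%. It was 38.4% with upper-quartile factors and 24.1% with library size only. The latter scaling moved the median log2 fold change of all genes to -0.20. The count was 1484 without vehicle replicate 1, 1308 without vehicle replicate 2 and 1212 without the unnumbered vehicle replicate. It was 1509 without iD1 replicate 2 and 1231 without iD1 replicate 3. Of the 2293 genes, 929 stayed called without each of the 6 libraries. Among the genes named above, Mt2 lost its call without vehicle replicate 2 or any 1 of the iD1 libraries. Mt1 lost it without vehicle replicate 2, iD1 replicate 2 or iD1 replicate 3, and Egr1 without vehicle replicate 2 or the unnumbered vehicle replicate. Ppp1r3g lost it without any 1 vehicle library or iD1 replicate 2, and Lcn2 without any 1 vehicle library, iD1 replicate 1 or iD1 replicate 3. Pnpla3 lost it without vehicle replicate 2, the unnumbered vehicle replicate, iD1 replicate 2 or iD1 replicate 3. Zfp872 lost it without any 1 vehicle library, iD1 replicate 2 or iD1 replicate 3. The adjusted p of these 7 genes without 1 library rose to between 0.0645 for Egr1 and 0.116 for Lcn2 at its highest.

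**Figure D2:**
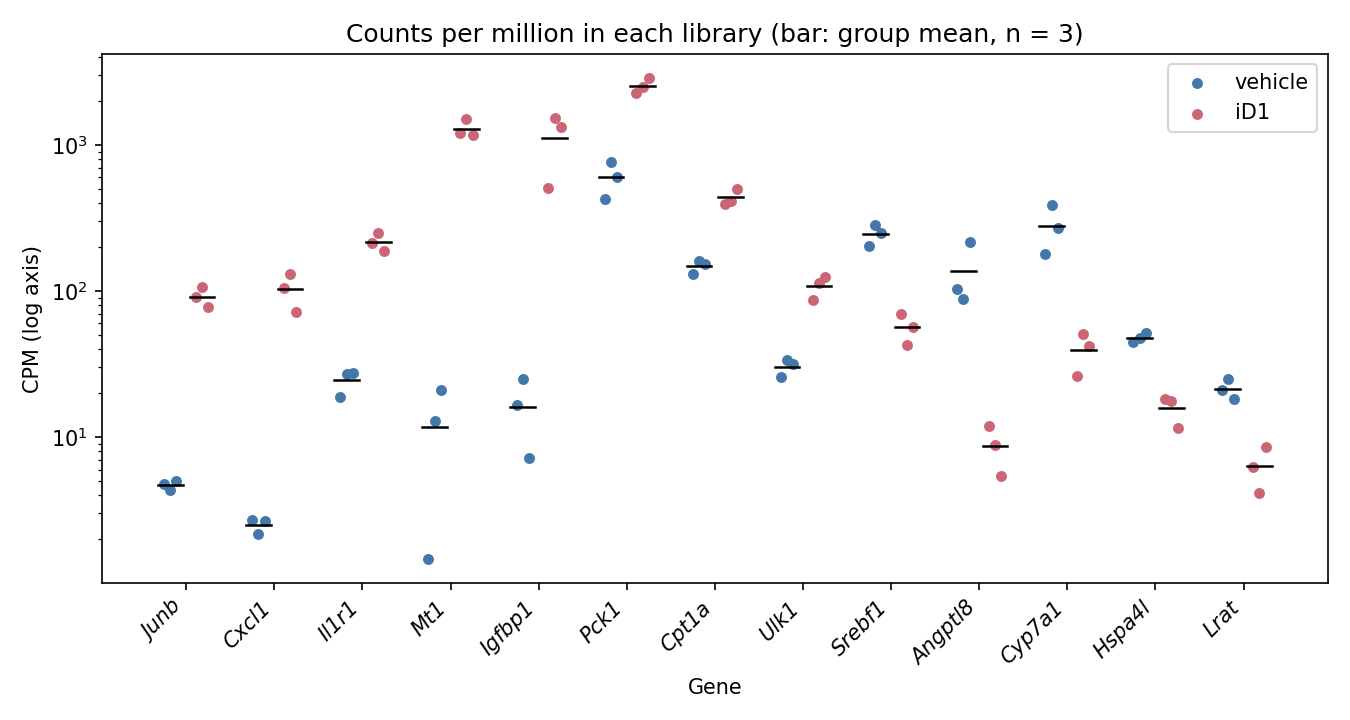
CPM of 13 genes in each library on a log axis, with 3 vehicle points and 3 iD1 points per gene and a bar at the group mean. Junb lies near 4.71 CPM in vehicle and 91.5 CPM in iD1 livers, and in each of the 13 genes the 2 groups do not overlap.

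By identifier, Junb (ENSMUSG00000052837) lies on chromosome 8 from 84974484 to 84978718 and Cxcl1 (ENSMUSG00000029380) on chromosome 5 from 90891241 to 90893115. Igfbp1 (ENSMUSG00000020429) lies on chromosome 11 from 7197782 to 7202546, Srebf1 (ENSMUSG00000020538) on chromosome 11 from 60199089 to 60222581 and Cyp7a1 (ENSMUSG00000028240) on chromosome 4 from 6265612 to 6275633. These positions are those of GENCODE M21 on GRCm38 and all 5 are protein-coding genes. The build behind the deposited counts is not given in the sources used here. Exons of Junb share 173 bases with Prdx2 on the other strand, which had a log2 fold change of 0.17, and exons of Srebf1 share 109 bases with Rai1, which had 0.04. Hspa1a and Hspa1b are near-identical copies whose reads the authors' counting could have split, so their single values are uncertain, as are those of Saa1 and Saa2 and of Cyp4a10 and Cyp4a31.

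Of 49 gene lists fixed before the data were examined, 48 had at least 5 tested members and 17 were called by camera with a preset inter-gene correlation of 0.01, 13 higher and 4 lower with iD1. None of the 17 was called with an estimated correlation, where the smallest adjusted p was 0.0660, and 11 of them were called by fry. Fry did not call the lists of cholesterol synthesis (adjusted p = 0.117), fatty acid synthesis and the urea cycle (0.103 each), heat shock (0.0822), complement (0.0696) and ribosomal proteins (0.458). Beside each list stands the count of its member genes called by edgeR.

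Of 25 tested acute phase genes, a list fixed for the liver's response to inflammation, 15 were higher and 0 lower. Adjusted over the list alone, 19 were higher. The median log2 fold change was 1.94, with camera's adjusted p = 1.25e-12 (adjusted p = 0.429 with an estimated correlation). The count higher was 10 without vehicle replicate 1 and 11 without vehicle replicate 2. It was 12 without the unnumbered vehicle replicate or iD1 replicate 3. The interleukin 1 receptor gene Il1r1 went from 24.5 ± 4.96 to 216 ± 30.7 CPM, the serum amyloid gene Saa4 from 231 ± 55.5 to 883 ± 45.3 CPM and the fibrinogen chain Fga from 1980 ± 238 to 7678 ± 3461 CPM (SD, n = 3). Saa1 and Saa2, chosen after their values were seen, were not called: Saa1 measured 117 ± 163 CPM in vehicle and 2350 ± 1336 CPM in iD1 livers, with a log2 fold change of 4.32 (SE 1.43). Of 11 tested NF-kB and inflammatory mediators, 5 were higher and 1 lower (8 and 1 adjusted over the list alone), including Cxcl1, from 2.51 ± 0.295 to 102 ± 29.7 CPM, and the inhibitor Nfkbia, from 20.2 ± 1.10 to 40.7 ± 5.38 CPM. The 1 lower was not called without the unnumbered vehicle replicate or iD1 replicate 3. That list's adjusted p was 2.02e-04 by camera (adjusted p = 0.373 with an estimated correlation). Of 32 interferon response genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), among them Oasl1 with a log2 fold change of -1.49 (SE 0.18) and Cxcl11, annotated as a polymorphic pseudogene, with -2.65 (SE 0.35). The camera adjusted p was 0.00307 (adjusted p = 0.373 with an estimated correlation), and 3 members were lower without vehicle replicate 2 or without iD1 replicate 3. With library size only 10 were lower, and without iD1 replicate 1 the counts were 2 higher and 6 lower. Beside these groups, the neutrophil transcripts Retnlg, S100a8 and S100a9 were called higher at no more than 2.54 CPM on average in iD1 livers. The call of S100a8 was lost without vehicle replicate 1 or the unnumbered vehicle replicate, and that of S100a9 without any 1 vehicle library or iD1 replicate 3.

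Immediate early genes, a list fixed as a sign of handling or acute stimulation, rose in 13 of 16 tested members with 0 lower (15 adjusted over the list alone). Junb, Btg2 and Jun had its smallest p-values, and Jun went from 12.5 ± 1.04 to 56.2 ± 11.5 CPM. By size Egr1 rose more than these, with a log2 fold change of 5.72 (SE 0.81). The camera adjusted p was 3.81e-12 (adjusted p = 0.0660 with an estimated correlation).

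Genes known to respond to glucocorticoids rose in 13 of 17 with 0 lower (14 adjusted over the list alone), with a median log2 fold change of 1.88 and camera's adjusted p = 2.68e-11 (adjusted p = 0.373 with an estimated correlation). They included Klf9, from 39.0 ± 8.50 to 104 ± 10.6 CPM, and the phosphatase Dusp1, from 25.7 ± 1.51 to 45.5 ± 3.24 CPM. Members not called included Fkbp5 with a log2 fold change of 1.54 (SE 0.59) and Tsc22d3 with -0.38 (SE 0.20), both chosen after their values were seen. Without iD1 replicate 2 or iD1 replicate 3 the count higher was 7. Without iD1 replicate 1 there were 9 higher and 1 lower, and without the unnumbered vehicle replicate 9 were higher.

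Genes of gluconeogenesis and fasting rose in 11 of 14 with 0 lower (12 adjusted over the list alone). Camera gave adjusted p = 1.83e-09 (adjusted p = 0.373 with an estimated correlation). Pck1, which commits oxaloacetate to glucose synthesis, went from 600 ± 170 to 2535 ± 310 CPM, and G6pc, which releases free glucose, from 144 ± 31.0 to 493 ± 184 CPM. PPAR-alpha targets and fatty acid oxidation genes rose in 18 of 30, with 1 lower (22 and 1 adjusted over the list alone) and camera's adjusted p = 3.80e-09 (adjusted p = 0.373 with an estimated correlation). Among them were Cpt1a, which admits fatty acids to mitochondria, from 148 ± 15.1 to 437 ± 57.8 CPM, Angptl4, from 41.9 ± 11.5 to 232 ± 25.7 CPM, and the hormone gene Fgf21, from 0.567 ± 0.30 to 4.44 ± 0.701 CPM. The member that fell was Acot3, an acyl-CoA thioesterase, from 16.5 ± 4.58 to 7.23 ± 0.962 CPM. Its exons share 396 bases on the same strand with Gm49366, which had a log2 fold change of -1.79 and was not called, so reads of the pair may be mixed. The fasting count was 7 without iD1 replicate 2, iD1 replicate 3 or the unnumbered vehicle replicate. The fatty acid oxidation count was 8 without iD1 replicate 3, 10 without vehicle replicate 2 and 6 without the unnumbered vehicle replicate.

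Part of the lipid synthesis genes fell. Of 20 genes of fatty acid and triglyceride synthesis, 8 were lower and 0 higher (10 lower and 1 higher adjusted over the list alone). The list's camera result was adjusted p = 1.76e-04 (adjusted p = 0.641 with an estimated correlation). Srebf1, a regulator of lipid synthesis, went from 245 ± 40.1 to 56.5 ± 13.3 CPM, and Gpam, which starts glycerolipid synthesis, from 187 ± 17.3 to 66.4 ± 19.2 CPM. Of 23 genes of cholesterol synthesis and SREBP2 targets, 8 were lower and 0 higher (8 adjusted over the list alone). Camera gave adjusted p = 8.32e-06 (adjusted p = 0.641 with an estimated correlation). Sc5d, a late enzyme of the pathway, went from 634 ± 59.3 to 266 ± 17.3 CPM and Insig1, a regulator of SREBP processing, from 607 ± 178 to 214 ± 51.4 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 278 ± 103 to 39.7 ± 12.4 CPM. The bile salt pump gene Abcb11 fell by 1.11 on the log2 scale and the phospholipid transporter gene Abcb4 rose by 0.79. They were the 3 called genes of 18 tested in the bile acid list (1 higher and 2 lower adjusted over the list alone), and 4 were higher without iD1 replicate 1. The fatty acid count was 14 without iD1 replicate 1, 4 without iD1 replicate 2, iD1 replicate 3, vehicle replicate 1 or the unnumbered vehicle replicate, and 3 without vehicle replicate 2. The cholesterol count was 14 without iD1 replicate 2.

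Of 17 glycolysis and glycogen genes, 2 were higher and 2 lower (3 and 2 adjusted over the list alone). The glycogen-targeting subunit Ppp1r3b fell by 1.32 on the log2 scale, from 535 ± 59.8 to 215 ± 61.6 CPM, and Ldha rose by 1.06. Only 1 was higher without any 1 vehicle library or iD1 replicate 2, and 4 were lower without iD1 replicate 1. Autophagy and lysosome genes rose in 8 of 25 with 0 lower (12 adjusted over the list alone). Camera gave adjusted p = 3.58e-06 (adjusted p = 0.373 with an estimated correlation). Examples are the autophagy kinase Ulk1, from 30.4 ± 4.28 to 108 ± 19.0 CPM, and Map1lc3b, from 51.3 ± 2.13 to 133 ± 26.6 CPM. Genes of the urea cycle and amino acid catabolism rose in 8 of 26 with 0 lower (11 higher and 2 lower adjusted over the list alone). By camera the list had adjusted p = 0.00271 (adjusted p = 0.693 with an estimated correlation). An example is Aass, which degrades lysine, from 243 ± 67.8 to 612 ± 100.4 CPM. That count was 4 without iD1 replicate 3 or vehicle replicate 1 and 5 without vehicle replicate 2 or the unnumbered vehicle replicate.

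Integrated stress response and ATF4 targets rose in 12 of 19 with 0 lower (12 adjusted over the list alone). The count higher was 8 without any 1 vehicle library or iD1 replicate 2. Camera gave adjusted p = 8.28e-06 (adjusted p = 0.373 with an estimated correlation). Sesn2 went from 2.87 ± 0.368 to 11.8 ± 3.02 CPM and Ppp1r15a from 5.92 ± 0.264 to 19.9 ± 5.85 CPM. In the heat shock list 8 of 18 genes were lower and 2 higher (8 and 3 adjusted over the list alone). The list's camera result was adjusted p = 0.0149 (adjusted p = 0.693 with an estimated correlation), a call lost without the unnumbered vehicle replicate (adjusted p = 0.0507). The falls included the cochaperones Fkbp4, from 180 ± 6.33 to 84.1 ± 6.83 CPM, and Stip1, and the chaperone Hspa4l, from 47.8 ± 3.62 to 15.8 ± 3.69 CPM. The 2 that rose were the stress-inducible Hspa1a, with a log2 fold change of 4.79 (SE 0.47), and Hspa1b, named after its values were seen. The count lower was 5 without iD1 replicate 2 or the unnumbered vehicle replicate. Of 16 p53 targets, 6 were higher and 3 lower (6 and 4 adjusted over the list alone). Trp53inp1 had a log2 fold change of 2.15 (SE 0.35) and Plk2 of -1.05 (SE 0.21). The list had camera's adjusted p = 0.0397 (adjusted p = 0.373 with an estimated correlation). Its call was lost without vehicle replicate 1 (adjusted p = 0.0531), the unnumbered vehicle replicate (0.0509) or iD1 replicate 2 (0.0501), on ranks (0.117) and with GC content and length trends removed (0.0857). In the iron, metallothionein and heme list 5 of 20 were higher and 2 lower (5 and 2 adjusted over the list alone). The zinc transporter Slc39a14 was higher and the transferrin receptor Tfrc lower. The list had camera's adjusted p = 0.0353 (adjusted p = 0.373 with an estimated correlation). This call was lost without iD1 replicate 1 (adjusted p = 0.0740), on ranks (0.0791) and with GC content and length trends removed (0.0857). The count higher was 1 without iD1 replicate 2 or iD1 replicate 3, 2 without vehicle replicate 2 and 3 without vehicle replicate 1, and the count lower was 1 without vehicle replicate 2, iD1 replicate 2 or iD1 replicate 3. Complement and coagulation genes were higher in 3 of 30 (0 adjusted over the list alone; camera's adjusted p = 0.00605, adjusted p = 0.641 with an estimated correlation). That count was 0 without vehicle replicate 1, the unnumbered vehicle replicate or iD1 replicate 2 and 1 without vehicle replicate 2 or iD1 replicate 3, and it was 1 with upper-quartile factors and 0 with library size only. No ribosomal protein gene was called among 32 (0 adjusted over the list alone). Their median log2 fold change was 0.14, and -0.07 with library size only, with camera's adjusted p = 0.0379 (adjusted p = 0.797 with an estimated correlation). The ribosomal call was lost without vehicle replicate 2 (adjusted p = 0.440) or iD1 replicate 2 (0.360), with the stricter CPM filter (0.0521) and with GC content and length trends removed (0.0632).

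**Figure D3:**
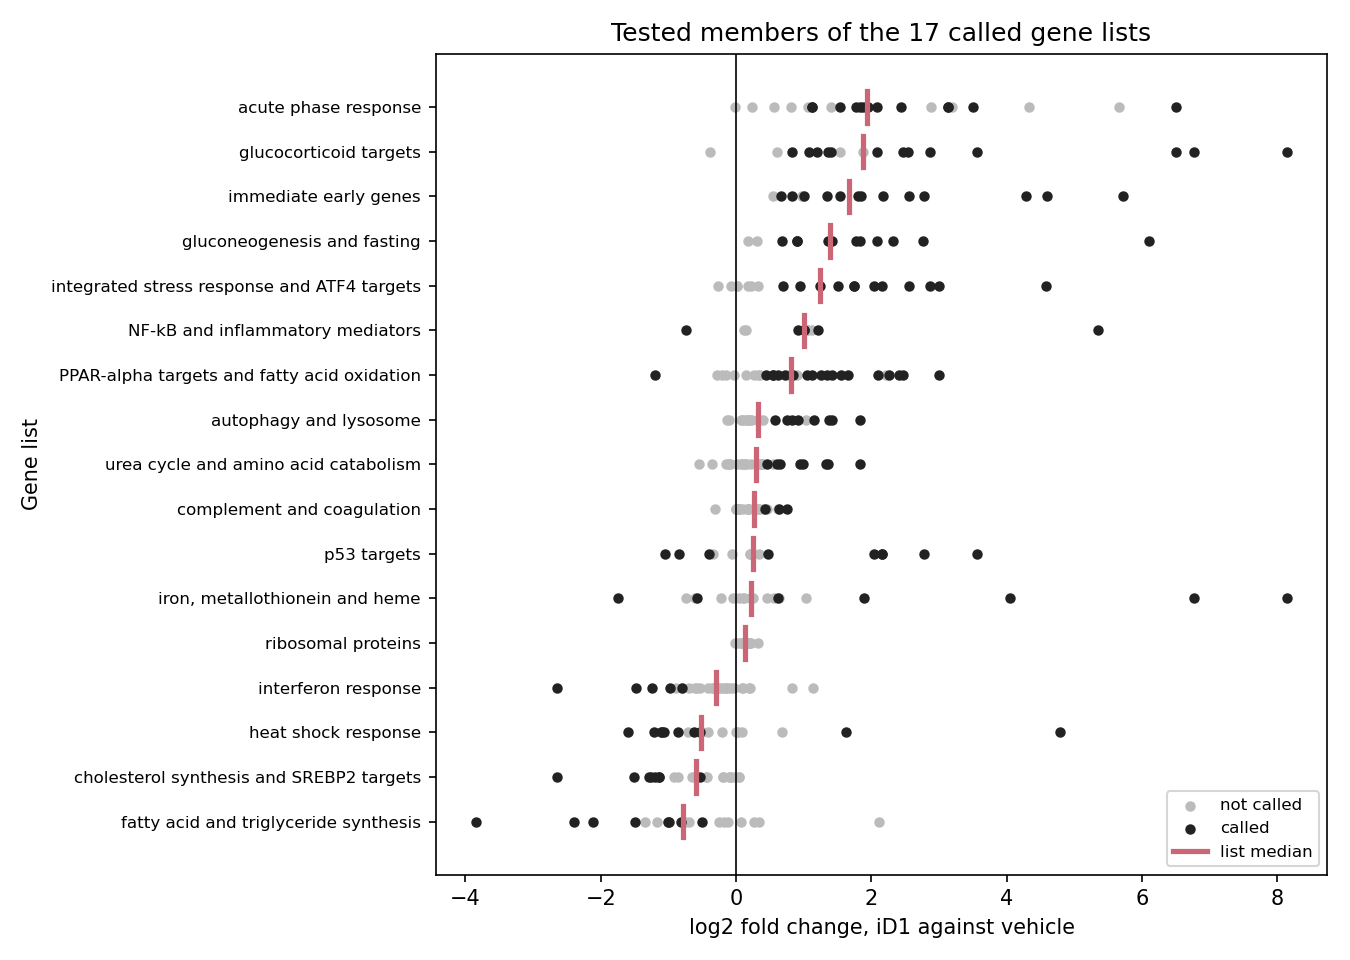
Log2 fold changes, iD1 against vehicle, of the tested members of the 17 gene lists called by camera, with called genes in black, other members in grey and the list median as a red bar. Medians run from -0.79 for fatty acid and triglyceride synthesis to 1.94 for the acute phase response, and no ribosomal protein gene is called.

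Markers of other cell types moved in part. Of 16 stellate cell and fibroblast markers, 4 were lower and 0 higher (4 adjusted over the list alone), including Lrat, which stores retinol in stellate cells, from 21.4 ± 3.44 to 6.34 ± 2.21 CPM, and Cxcl12, from 333 ± 13.5 to 201 ± 6.50 CPM. Of 17 liver endothelial markers, 3 were lower (4 adjusted over the list alone), including Gpr182 with a log2 fold change of -0.82 (SE 0.15). That count was 1 without any 1 of the vehicle libraries. Of 17 Kupffer cell and macrophage markers, 1 was lower (1 adjusted over the list alone), the iron exporter Slc40a1, which hepatocytes also express. Its call was lost without vehicle replicate 2, iD1 replicate 2 or iD1 replicate 3, and 3 of the markers were lower without vehicle replicate 1 or with library size only. Of 10 monocyte and neutrophil markers, 3 were higher (3 adjusted over the list alone), a count of 1 without vehicle replicate 1 or the unnumbered vehicle replicate. By edgeR 0 were called among 6 T and NK cell markers or 5 B and plasma cell markers (0 adjusted over the list alone in both). In the mitochondrially encoded list 0 of 13 genes were called (0 adjusted over the list alone), with a median log2 fold change of -0.16. With library size only 3 of them were lower and the median was -0.35, and with GC content and length trends removed the median was 0.014. In the main fit camera called none of these lists, with an adjusted p of 0.121 for the monocyte and neutrophil list, 0.134 for the stellate list and 0.141 for the Kupffer list. It called the Kupffer list lower without vehicle replicate 1 (adjusted p = 3.87e-04) or iD1 replicate 3 (0.0341), the stellate list lower without iD1 replicate 3 (0.0235) and the mitochondrially encoded list lower without vehicle replicate 1 (0.0318). Fry called the monocyte and neutrophil list higher (adjusted p = 0.0343).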

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

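Apart from the GC content and length correction, chosen after the data were seen, the alternatives were planned. Against 2293 called genes (1155 higher, 1138 lower, 908 at least 2-fold), the count stayed within 1.5 times under RLE factors, upper-quartile factors, DESeq2, limma-voom, both other filters, thinning, non-robust shrinkage and the GC content and length correction, from 2199 to 2591. With library size only, 597 genes were higher and 1883 lower, since that scaling shifted the median of all genes by -0.20 on the log2 scale. An adjusted p under 0.01 left 825 genes, 458 higher, 367 lower and 508 at least 2-fold, and glmTreat against a fold of 1.2 left 1278, 650 higher and 628 lower, both stricter by construction. Leaving out 1 library gave 1212 to 2574 genes, with 592 to 1201 higher and 578 to 1373 lower. Fewer samples lower the number by construction, but the rise to 2574 without iD1 replicate 1 goes the other way, and its cause was not tested. In 0 of the settings did a shared called gene change direction. The fits share most or all of their libraries, which made such a change unlikely beforehand.

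With the replicate block 827 genes were called, 434 higher and 393 lower, and 749 of them were among the 2293. The fit spends degrees of freedom on the numbers, and since only the numbers 1 and 2 occur in both groups, it leaves 1 residual degree of freedom. The deviations of same-numbered libraries from their group means correlated at 0.17 across genes for number 1 and at -0.13 for number 2. Pairs that do not share a number ran from -0.245 to 0.218. The correlations therefore do not show whether a number marks anything that the samples share. With the block 22 lists were called, 16 of them among the 17. The heat shock list was lost (adjusted p = 0.159), and the lists of CAR and PXR targets, aryl hydrocarbon receptor targets, monocytes and neutrophils, B and plasma cells, endothelium and stellate cells were gained, with adjusted p from 0.0145 to 0.0465.

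Of 17 called lists, 0 were called with an estimated correlation. Other settings gave 14 to 22 called lists. Of 136 named called genes, 93 stayed called without each library and 43 lost the call without at least 1, and 0 changed sign under another scaling. Another scaling moved the median of all genes by -0.20 at most, less than the changes of these genes, so a turn was hardly possible. The self-test recovered 18.2% of single genes changed 1.5-fold and 12% of the members of raised lists, with 13418 of 13718 simulated genes unchanged. A larger share, 16.7% of the tested genes, was called in the real data, which makes the adjusted threshold less strict. The self-test therefore does not give the recovery of such changes in these livers.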

Other observations

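The tests of white blood cell RNA, of the time of day and of single iD1 libraries and the GC content and length correction were chosen after the data had been looked at, and the others before.

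Further lists moved in part. Of 25 CAR and PXR drug metabolism targets, 4 were higher and 1 lower (4 and 1 adjusted over the list alone), including Por, which supplies electrons to cytochromes P450, from 256 ± 98.3 to 841 ± 111 CPM. The 1 lower was called in 0 of the 6 leave-one-out fits. Of 7 aryl hydrocarbon receptor targets 3 were higher (3 adjusted over the list alone), including Tiparp, whose call was lost without vehicle replicate 2 or iD1 replicate 3. Of 19 NRF2 targets 4 were higher (4 adjusted over the list alone), including Osgin1 at a log2 fold change of 0.93 (SE 0.14). The NRF2 count was 2 without vehicle replicate 1, the unnumbered vehicle replicate, iD1 replicate 2 or iD1 replicate 3. Both sterol transporters Abcg8 and Abcg5 were higher, 2 of 10 LXR targets (2 adjusted over the list alone), but Abcg5 kept its call in only 1 of 6 leave-one-out fits, the one without vehicle replicate 1 (adjusted p up to 0.121 in the others). Exons of the pair share 82 bases on opposite strands. Of 18 circadian clock genes 2 were higher and 3 lower (4 and 3 adjusted over the list alone), with Nfil3 at 1.62 (SE 0.23) and Per2 at -1.60 (SE 0.20), but 1 higher without vehicle replicate 1 or iD1 replicate 3 and 1 lower without vehicle replicate 2. Of 17 hypoxia targets 6 were higher and 2 lower (7 and 3 adjusted over the list alone), including Ndrg1 at 1.73 (SE 0.23), with 3 higher without iD1 replicate 3. The count of hypoxia targets lower was 4 without iD1 replicate 1, 1 without vehicle replicate 1 or 2, and 0 without any 1 of the other libraries. Of 14 thyroid hormone targets 3 were higher and 3 lower (4 and 4 adjusted over the list alone), with Bcl3 at 1.74 (SE 0.23), and 1 lower without vehicle replicate 1, vehicle replicate 2, iD1 replicate 2 or iD1 replicate 3. Of 19 pericentral genes 3 were higher and 1 lower (8 and 3 adjusted over the list alone), and of 17 periportal genes 3 were higher and 1 lower (4 and 2 adjusted over the list alone), the last being Cdh1 at -1.49 (SE 0.15).

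Few members were called in the other lists. In the hepatocyte identity list 3 of 16 were higher and 1 lower (4 and 1 adjusted over the list alone), the last being Cebpa, whose call was lost without iD1 replicate 3. Only 1 was higher without any 1 library other than iD1 replicate 1, without which 3 were lower. Of 24 male-biased growth hormone targets 2 were lower (2 adjusted over the list alone), including Igfals at -0.96 (SE 0.16), and of 13 female-biased genes 1 was lower (1 adjusted over the list alone), or 3 without vehicle replicate 1. Of 15 YAP and TAZ targets 1 was higher and 1 lower (1 and 1 adjusted over the list alone), the latter Ajuba at -1.94 (SE 0.19). Of 18 matrix genes 2 were higher (2 adjusted over the list alone), including Fn1 at 1.23 (SE 0.26), whose call was lost without the unnumbered vehicle replicate. The counts were 1 higher of 20 ER stress genes (1 adjusted over the list alone), Herpud1, 1 higher of 24 cell cycle genes (1 adjusted over the list alone), Ccne1, and 1 lower of 9 MHC class II genes (1 adjusted over the list alone), Ciita, whose call was lost without vehicle replicate 2 or iD1 replicate 3. Exons of Ciita share 329 bases with Dexi on the other strand, which was also called lower, at -0.95. Of 8 cholangiocyte markers 1 was higher and 1 lower (1 and 1 adjusted over the list alone), the former Sox9, called only in the fit without iD1 replicate 3 among the 6 leave-one-out fits (adjusted p up to 0.125), and the latter Krt19 at -2.66 (SE 0.41), with 2 lower without iD1 replicate 1. By edgeR 0 genes were called among 26 nuclear-encoded respiratory chain genes, 6 mesothelial markers and 7 adipocyte and muscle genes (0 adjusted over the list alone in each) and among 6 erythroid genes (1 higher and 1 lower adjusted over the list alone). Of 2 tested pancreatic acinar genes 1 was higher (1 adjusted over the list alone), Cela2a, at 0.704 ± 0.289 CPM in iD1 livers, whose call was kept only without iD1 replicate 1 (adjusted p up to 0.167 in the others). These counts rest on few genes. The widest moves were 6 ER stress genes lower without iD1 replicate 2, 5 pericentral genes lower without iD1 replicate 1 and 4 erythroid genes higher without vehicle replicate 1, while 0 aryl hydrocarbon receptor targets were called without iD1 replicate 3 and 1 without the unnumbered vehicle replicate or iD1 replicate 2. Without vehicle replicate 1, 2 matrix genes and 2 YAP and TAZ targets were lower, and without iD1 replicate 1, 5 pericentral genes and 2 YAP and TAZ targets were higher. With library size only, 4 YAP and TAZ targets and 3 matrix genes were lower, 1 hepatocyte identity gene was higher and 2 were lower, and 1 LXR target was higher and 1 lower. Higher pericentral genes numbered 5 with RLE factors and 6 with GC content and length trends removed. In the main fit none of these lists was called by camera with the preset correlation, and the pancreatic list was too small to test. The CAR and PXR list, at adjusted p = 0.0509, was called higher without vehicle replicate 2, the unnumbered vehicle replicate or iD1 replicate 1 (adjusted p = 0.0138, 0.0177 and 0.00471). The respiratory chain list was called higher without the unnumbered vehicle replicate or iD1 replicate 1 and on ranks, the NRF2 and erythroid lists higher without vehicle replicate 1, and the aryl hydrocarbon receptor list higher with the stricter CPM filter. The ER stress list was called lower without iD1 replicate 2 and the MHC class II list lower without iD1 replicate 3. Fry called the LXR and NRF2 lists higher (adjusted p = 0.0184 and 0.0165).

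The number of called genes was weighed against chance, depth and sequence composition. The real split of the 6 libraries gave 2293 called genes and 1 of 10 splits gave as many, the highest of the others being 0. However, 10 splits cannot give a share under 0.05. The other splits mix the groups, so the group difference adds to the spread within their sides and can by itself remove calls. The 0 is therefore no measure of what chance gives. With the libraries thinned to the smallest total count, 91.8% of the called genes stayed called, and 95.8% did with each library's trend on GC content and length removed, which argues against total depth or these trends as the whole cause. For the called lists, the real split gave 17, 3 of the 10 splits gave at least 17, and the highest of the others gave 19. Each of the other splits sets 2 libraries of a group with 1 of the other and so keeps part of the group difference, which leaves open how many of its lists owe to that. The estimated correlation between members of the called lists ran from -0.00822 in p53 targets to 0.705 in ribosomal proteins, and none was called with it. Immediate early genes, at -0.00585, and p53 targets lay below the preset 0.01 and still lost their calls. With an estimate, camera also takes its degrees of freedom from the libraries and not from the genes. The loss of these calls therefore cannot be laid to correlated members. In the other called lists the correlation and the degrees of freedom cannot be told apart.

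The rise of 15 acute phase genes may come from the liver's own cells or from white blood cells in it. Over the iD1 libraries, S100a8 and S100a9, among the most abundant neutrophil transcripts, together reached at most 2.28% of the CPM of Lcn2. This argues against neutrophil RNA as the source of the Lcn2 rise. The fibrinogen genes Fga, Fgb and Fgg, which white blood cells lack, were called higher, so their rise does not come from such cells. For the other called acute phase genes the source was not tested. Lcn2 varied between iD1 libraries, at 146, 676 and 87.5 CPM. What set off the response was not tested, and handling, injection and the compound stay open.

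Members of the fasting and glucocorticoid lists were higher and part of the lipid synthesis lists lower, with list calls that were lost with an estimated correlation (adjusted p = 0.373 and adjusted p = 0.641). This may reflect lower food intake or a stress response in the iD1 mice, neither of which was measured, or a different time of collection. The mean log2 fold change of 5 clock genes that peak at night minus that of 6 that peak by day was -0.42 (SE 0.43 over genes), which does not settle the time of day. For each library the median log2 difference over all tested members was taken. An iD1 library was set against the mean of all vehicle libraries, and a vehicle library against the mean of the other vehicle libraries. At least 2 iD1 libraries lay beyond all vehicle libraries by more than 2 SD of the vehicle values in 5 of 5 lists. These were the fasting, glucocorticoid, lipid synthesis and fatty acid oxidation lists. This argues against a single iD1 library as the source. The iD1 libraries were not alike, with medians in replicates 1, 2 and 3 of -0.23, -1.05 and -1.14 for fatty acid synthesis and of -1.25, 0.14 and -0.91 for cholesterol synthesis.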
